A study of Arabidopsis thaliana with 6 samples.

How the data were processed

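Transcript levels were measured with Affymetrix ATH1 arrays in whole seedlings of Arabidopsis thaliana, wild type (Columbia-0) and the lcbk1-2 mutant, before cold (0 h, 22 °C) and after 3 h and 24 h at 4 °C. There were 6 arrays, 1 for each genotype and time, so no condition had replicates. The labels do not say whether an array came from 1 culture or from pooled cultures, and they give no time of day. No seedlings kept at 22 °C were measured at 3 h or 24 h, so the cold cannot be separated from the time of day or the age of the plants. If sampling ran from 1 start, 0 h and 24 h fall at the same time of day, but 3 h does not.

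Biotin-labelled target was made from 6 µg of total RNA, per the labels' protocols. The authors deposited 1 intensity per probe set and array, a MAS5 signal per the submitters' processing notes; the MAS5 version and its settings are not given in the sources used here. From the values, the deposited intensity is linear, not log-transformed, and its 2% trimmed mean is the same on all 6 arrays, so each array had been scaled to a common mean. Detection calls and the raw image files were not used here.

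The table held 22810 features, of which 64 control probe sets were set aside. Probe sets were named through the platform's annotation as supplied and the RefSeq gene table of assembly TAIR10.1; no coordinates are given. Of the 22746 remaining probe sets, 13513 were annotated to 1 gene (13436 of them matched a locus in the gene table), 503 to several genes and 8730 to none. Probe sets without an annotation stayed in the tests and are called unnamed here; those of several genes stayed in the tests and are not named. Many well-studied genes are among the unnamed ones, so their absence from the text says nothing about their expression. For a gene with more than 1 probe set, the one with the highest mean was kept, which set aside 157 and left 22589 features.

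Values below a floor, the 35th percentile of all values of the 6 arrays pooled (a signal of 65.9), were set to it, and log2 values were taken with no further scaling. Features above the floor on at least 2 arrays were tested: 15658, of which 8473 were annotated to 1 gene, 316 to several and 6869 to none. Where a group lay at the floor on all its arrays, a fold change is a lower bound and is given as "at least". Values set to the floor do not vary, so the SE and p of such a feature can be too small.

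The fit across genes used limma 3.58.1 in R 4.3.3 with genotype and time as additive terms, moderated by empirical Bayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It gave the change at 3 h and at 24 h against 0 h and from 3 h to 24 h, each shared by both genotypes, and the difference of lcbk1-2 from wild type shared by the 3 times. It left 2 residual degrees of freedom (prior degrees of freedom 4.16, prior SD 0.158 on the log2 scale). The spread behind each SE and p therefore holds the array error together with any difference between genotypes in the response to cold, and not the spread between replicates. Comparisons of 1 array against 1 (the cold change within a genotype, and lcbk1-2 against wild type at each time) have no test; features at least 2-fold apart were counted.

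Before the data were examined, 21 lists of 351 Arabidopsis loci were fixed. Of these loci 53 were on annotated probe sets of 1 gene and 49 were tested. A gene is called measured below if it was tested on such a probe set. Other genes of a list or family may lie on unnamed probe sets. Of the 21 lists, 5 had no tested member (abscisic acid, morning clock genes, membrane lipids, reproductive markers and senescence) and 9 had 1 or 2, whose members are given singly. The other 7 were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists and the 4 contrasts and with an estimated correlation beside it. The estimated form rests on the 2 residual degrees of freedom of the fit, which leaves it little power. A list that did not pass it is therefore not argued against by it. The preset value, in turn, was not taken from these arrays. After the data had been examined, 22 gene families and organelle genomes were added by gene symbol or locus and tested in the same way, adjusted apart. In comparisons of 1 array against 1, a list's median is described by its percentile among 10000 random lists of the same size, matched on mean expression in 10 bins; such lists ignore that genes of a family move together.

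The rule for named genes was fixed before the data were examined. It takes LCBK1 and the sphingolipid list; for each shared change, the 10 largest rises and the 10 largest falls among annotated genes past the threshold that changed at least 2-fold in the same direction in each genotype; for lcbk1-2 against wild type at each time, the 10 highest and the 10 lowest whose brighter array lies at least 4 times above the floor; and the members of the lists. Genes named outside the rule are marked as chosen after their values were seen. The floor, the filter, the fit, the thresholds and the alternatives below were also fixed before the data were examined. The hypotheses of the closing part were formed afterwards.

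The calculations were tested on simulated data made from the 15658 tested features, with 50 features changed at each of 4 sizes. The changed features and the list members were drawn from those with a mean above 4 times the floor. Errors were independent between genes, with no difference between genotypes in the response to cold. The shares therefore do not cover dimmer features, and the list results do not cover genes that move together. Each simulated comparison held 200 changed features, and 116 to 129 features passed. In the data 2687 to 7487 passed for the cold changes and 2 for the genotype. The adjusted threshold depends on such counts, so the shares do not give the power in these arrays. Camera with an estimated correlation was not simulated. For the change at 3 h, 38% of the 2-fold and 96% of the 4-fold changes were recovered, with 11 false calls; at 24 h, 34% and 94%, with 6 false calls; from 3 h to 24 h, 28% and 94%, with 4 false calls; and for the genotype, 54% and 86%, with 4 false calls. In each of the 4 comparisons camera at the preset correlation recovered 20 of 20 shifted lists and called 0 of 20 unshifted ones. Against random lists, 20 of 20 shifted lists lay above the 95th percentile in each, and 5, 0, 0 and 1 of 20 unshifted ones lay outside percentiles 5 to 95 (3 h, 24 h, 3 h to 24 h, genotype).

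The alternatives were quantile normalization, scaling to a common median, floors at the 20th and the 50th percentile or none, a pseudocount of the size of the floor in its place, no filter on low probe sets, the mean over a gene's probe sets, an added 2-fold threshold (3-fold for counts without a test), eBayes with a mean-variance trend or in its robust form, time or genotype alone in the fit, an estimated correlation for the lists, and each array left out in turn. After the data had been examined, lists in the genotype comparison were also tested without members at the floor on all arrays of 1 genotype.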

Results

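Transcript levels were recorded on 6 ATH1 arrays in whole Arabidopsis seedlings aged 2 weeks, grown on medium with 2% sucrose under 16 h of light and 8 h of dark. The wild type (Columbia-0) was set beside lcbk1-2, labelled a knock-out mutant. LCBK1 is a long-chain base kinase, an enzyme that phosphorylates sphingoid bases, the backbones of sphingolipids. Each genotype was sampled at 22 °C (0 h) and after 3 h and 24 h at 4 °C. There was 1 array per genotype and time, and the number of arrays limits the precision of every value. The annotation assigned 0 probe sets to LCBK1 (AT5G23450). The targeted transcript was therefore not checked, and the genotype of each array rests on its label. The median signal of the arrays lay between 144 and 171, and 63.6% to 66.1% of the probe sets lay above the floor. Across genes, which are not independent replicates, the log2 signals of the genotypes at the same time correlated at 0.985 to 0.986, and those of 0 h and 24 h at 0.853 to 0.857. The first principal component, with 70.8% of the variance, ordered the arrays by time, and the third, with 4.34%, separated the genotypes. The hybridization controls of the wild-type 0 h array read 2.21 times the median of the other 5 arrays, which lay between 0.863 and 1.11 times theirs. The ratio of 3' to 5' signal of the actin control lay between 2.87 and 4.00, highest on the lcbk1-2 3 h array. Those of the GAPDH and ubiquitin controls lay between 1.08 and 1.31 and between 0.991 and 1.27.

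The comparison of 3 h at 4 °C with 0 h asks which transcripts respond early to cold. STZ, a zinc-finger transcription factor, was the only member of the list of first-wave cold transcription factors tested on a named probe set. It rose 16.4-fold (log2 change 4.03, SE 0.14, adjusted p = 1.7e-04 in limma). Its signal went from 317 to 5030 in the wild type and from 339 to 5741 in lcbk1-2. PUB19, a ubiquitin ligase, rose by 4.24 on the log2 scale, and CML38, a calmodulin-like protein, rose by 3.48. CML38 was chosen after its values were seen. Among annotated genes, by the rule for named genes, the largest rise belonged to AT5G62360 (log2 change 5.17, SE 0.15), followed by AT3G44450 at 4.74 and AT1G70420 at 4.55. AT4G27657 and AT1G11210 lay at the floor at 0 h in both genotypes and rose at least 21.1-fold and at least 19.7-fold. AT4G27652, AT3G28270 and AT3G04640 rose by 3.61 to 4.15. IAA29, a gene of the auxin and growth list, fell from a signal of 554 to 70.4 in the wild type and from 700.1 to below the floor in lcbk1-2 (log2 change -3.19, SE 0.16, adjusted p = 3.3e-04). AKINBETA1, a subunit of the energy-sensing kinase SnRK1, changed by -2.56. Other large falls were those of AT1G33055 (-3.51), AT3G23880 (-2.98), AT3G26510 (-2.78), AT5G02540 (-2.53), AT3G07350 (-2.48), AT3G10020 (-2.45) and AT4G28240 (-2.43).

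Among the lists fixed beforehand, all 6 measured cold-regulated (COR) effector genes had risen by 3 h, with a median log2 change of 1.23. All 6 also passed when adjusted over the list alone. The dehydrin gene LTI30 rose by 1.02, COR15A, whose product protects chloroplast membranes, by 1.43, COR15B by 1.99, and the dehydrin gene COR47 by 0.68. Camera at the preset correlation placed the list above other genes (adjusted p = 3.0e-04), and adjusted p = 0.356 with an estimated correlation. Of 5 measured auxin and growth genes 4 fell, and 4 when adjusted over the list alone, with a median of -1.64. They were IAA29, the auxin-conjugating enzyme genes GH3.3 (-2.53) and WES1 (-1.64), and the expansin gene EXPA8 (-1.56). HAT2 did not pass, at -0.18. The list's adjusted p was 1.7e-04 in camera and adjusted p = 0.356 with an estimated correlation. In the flavonoid list, 2 of 5 rose, the glucosyltransferase gene UGT78D2 by 2.74 and the anthocyanin glucosyltransferase gene AT4G14090, at the floor at 0 h, at least 2.43-fold. With a floor at the 50th percentile the call of AT4G14090 was lost, at 0.23. When adjusted over the list alone 3 passed, with DFR (0.67) as the third (camera adjusted p = 0.0113; adjusted p = 0.402 with an estimated correlation). The evening clock gene GI rose 2.14-fold. Both measured genes of starch and sucrose metabolism rose, the starch-phosphorylating enzyme PWD (AT5G26570) by 0.62 and the sucrose-phosphate synthase ATSPS4F by 1.25. The calls of PWD, of PORB and of EIN3 at 3 h were lost with a floor at the 20th percentile, and those of PWD and PORB also with none, at the same changes. In the sphingolipid list TSC10A, a reductase of long-chain base synthesis, changed by -0.88, and the ceramidase-like AT2G38010 by 0.61, a call lost under median scaling. Adjusted over the list alone, LCB2 (-0.58) also passed (camera adjusted p = 0.352; adjusted p = 0.726 with an estimated correlation). EIN3, a regulator of ethylene responses and of the CBF genes, changed by -0.73, while SIZ1, of the same list, passed only when adjusted over the list alone (-0.38). PORB, a chlorophyll synthesis gene, changed by -0.74, the only call among 4 photosynthesis genes (2 when adjusted over the list alone, with LHCB4.2 at -0.48; camera adjusted p = 0.0930, adjusted p = 0.536 with an estimated correlation).

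Over all 15658 tested features, 2687 passed at 3 h, 1453 higher and 1234 lower, of which 668 and 386 changed at least 2-fold. The count was 124 with no filter on low probe sets; with 1 array left out, which leaves 1 residual degree of freedom, it was 24, 486 and 0 without the wild-type arrays of 0 h, 3 h and 24 h and 3, 248 and 0 without those of lcbk1-2, each 0 in limma beside 4854 at an unadjusted p under 0.05 (5158 with all arrays). Of the COR calls at 3 h, COR27, LTI30, COR47 and COR15A were lost with a floor at the 20th percentile or none, at log2 changes as large or larger (1.44, 1.02, 0.68 and 1.43), COR27 (0) and AT4G33980 (0.45) with a floor at the 50th, and all 6 with no filter.

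**Figure D1:**
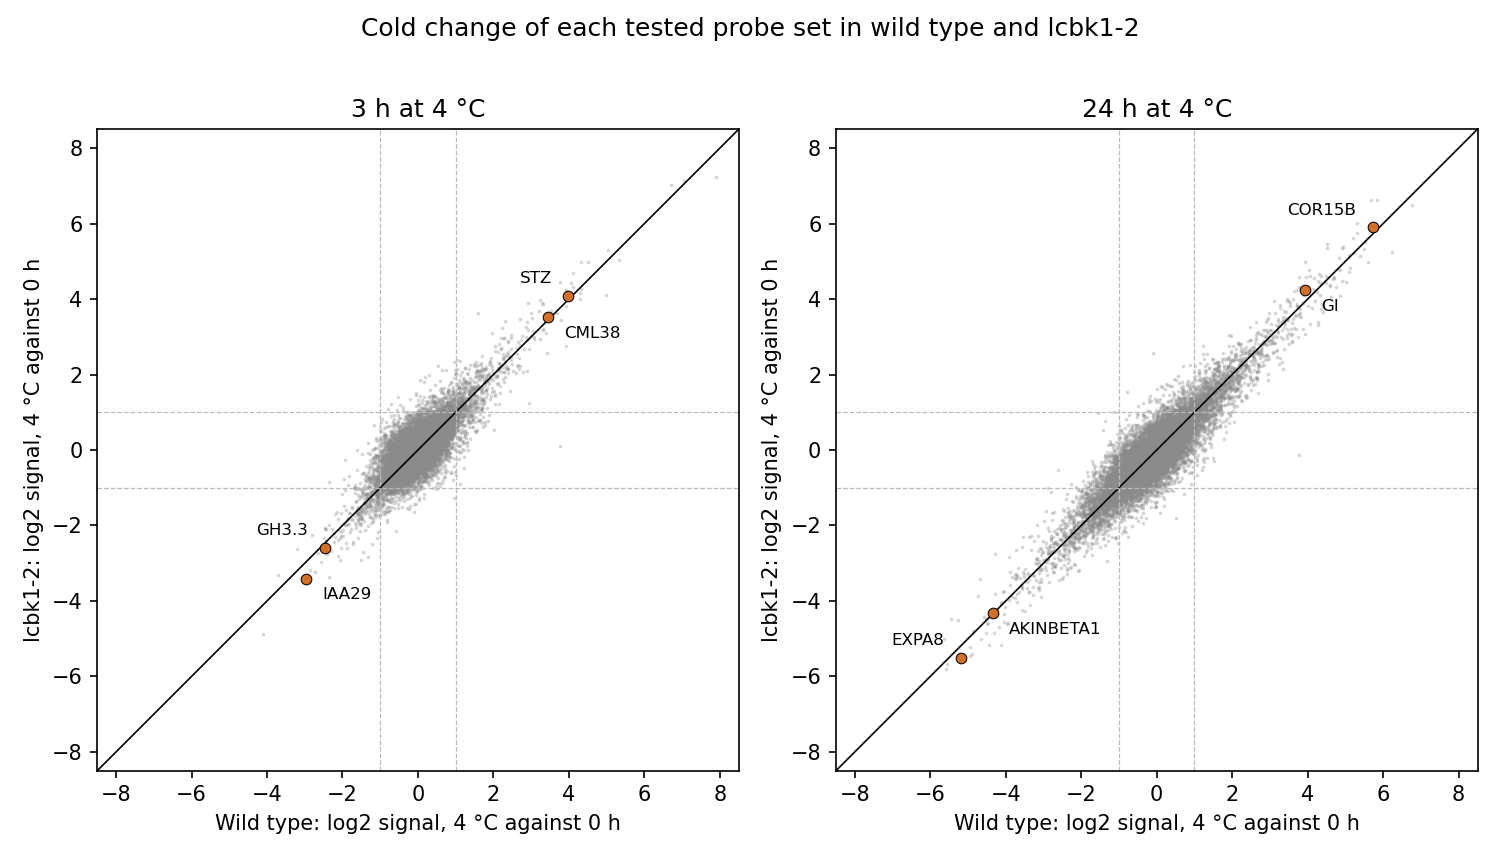
Each point is 1 of the 15658 tested features, with its log2 change against 0 h in the wild type (x axis) and in lcbk1-2 (y axis) after 3 h and 24 h at 4 °C, 1 array against 1; the solid line marks equal change and the dashed lines a 2-fold change. The features lie along the line of equal change, with a correlation across features of 0.797 at 3 h and 0.910 at 24 h.

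After 24 h at 4 °C, 3 of the COR genes stood among the 10 largest rises by the rule for named genes, and EXPA8 of the auxin and growth list among the 10 largest falls. COR15B rose 56.2-fold (log2 change 5.81, SE 0.19, adjusted p = 2.7e-05 in limma). Its signal went from 345 to 18196 in the wild type and from 338 to 20207 in lcbk1-2. COR15A rose by 5.74 and COR27, a repressor linked to the clock and the cold, by 5.52 on the log2 scale. The expansin gene EXPA8 fell from 2719 to 75.0 in the wild type and from 2984 to below the floor in lcbk1-2 (log2 change -5.34, SE 0.15, adjusted p = 2.7e-05). The largest rise was that of AT1G16850 (6.24, SE 0.21), then AT1G51090 (6.15). AT1G48100 (5.65), AT5G62360 (5.42), AT3G17130 (5.27) and AT3G44450 (5.21) also rose. AT2G22590 was at the floor at 0 h in both genotypes and rose at least 42.4-fold. The deepest fall was that of AT4G27450 (-5.62, SE 0.14), followed by AT5G19120 (-5.15), AT2G20670 (-4.96), the transcription factor gene BZIP61 (-4.68), AT2G34620 (-4.42), AKINBETA1 (-4.33), AT1G23390 (-4.31), AT4G01330 (-4.29) and AT5G62280 (-4.05).

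All 6 COR genes rose at 24 h, over all genes and adjusted over the list alone, with a median of 4.51 (camera adjusted p = 1.1e-05; adjusted p = 0.356 with an estimated correlation). LTI30 reached a signal of 44269 in the wild type and 39754 in lcbk1-2, and COR47 47260 and 42457. AT4G33980 was at the floor at 0 h and rose at least 9.07-fold. All 5 auxin and growth genes fell, over all genes and adjusted over the list alone, with a median of -3.10. Beside EXPA8, these were IAA29, at the floor at 24 h and at least 9.45-fold lower, WES1 (-3.10), the homeobox gene HAT2 (-2.28) and GH3.3 (-1.99) (camera adjusted p = 5.9e-04; adjusted p = 0.356 with an estimated correlation). Of 10 measured sphingolipid genes 5 fell and 1 rose, or 5 and 2 when adjusted over the list alone. Under median scaling 5 fell and 3 rose, AT2G38010 and AT1G01230 beside ATCES1. The falls included genes of the first steps of long-chain base synthesis: LCB2, a subunit of serine palmitoyltransferase (-1.83, SE 0.17, adjusted p = 4.2e-04), and both reductase genes of the next step, TSC10A (-1.63) and TSC10B (-1.23, a call lost with a floor at the 50th percentile, at -0.12). The ceramidase-like AT1G07380 (-0.86) and the glucosylceramide synthase AT2G19880 (-1.29) also fell. The alkaline ceramidase-like ATCES1 rose by 0.51, a call lost under quantile normalization and with a floor at the 20th percentile or none, AT2G38010 (0.42) passed only when adjusted over the list alone, and DPL1, the lyase that degrades phosphorylated long-chain bases, did not pass, at -0.44. The list's median of -0.65 did not stand apart from other genes in camera (adjusted p = 0.293; adjusted p = 0.726 with an estimated correlation).

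GI rose by 4.08 at 24 h, UGT78D2 by 4.03 and AT4G14090 at least 1.85-fold, these last being 2 of 5 flavonoid genes over all genes and adjusted over the list alone (camera adjusted p = 0.133; adjusted p = 0.597 with an estimated correlation). The call of AT4G14090 was lost with a floor at the 50th percentile, at 0.09. NDB2, an alternative NADH dehydrogenase of mitochondria, rose by 1.18, PWD by 1.16, ATSPS4F by 0.82 and STZ by 2.26. LHCB4.2, a light-harvesting protein gene, fell by 1.00 on the log2 scale, the only call among 4 photosynthesis genes, and 1 when adjusted over the list alone (camera adjusted p = 0.645; adjusted p = 0.726 with an estimated correlation). The small heat shock protein gene AT2G29500 changed by -0.96 and EIN3 by -0.97. SIZ1, a SUMO ligase (-0.45), and the root hair genes EXPA7 (-0.54) and EXPA18 (-0.49), 2 of 3 root markers, also fell, over all genes and adjusted over their lists alone, but these calls were lost under quantile normalization, median scaling and several other alternatives, and SIZ1 was at -0.06 as the mean over its probe sets. The third root marker, PYK10, did not pass, at -0.06 (root list camera adjusted p = 0.634; adjusted p = 0.726 with an estimated correlation). Among 3 reference genes PEX4 rose by 0.81, while AT4G34270 (-0.45, past the threshold when adjusted over the list alone) and AT2G28390 (-0.17) did not pass over all genes (camera adjusted p = 0.843; adjusted p = 0.864 with an estimated correlation). The defence genes SAG101 (-0.11) and WRKY53 (0.39), the jasmonate marker PDF1.2 (0.28), AT2G21640 of the oxidative stress list (0.07) and the mitotic kinase gene AUR1 (-0.30) did not pass at 24 h.

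At 24 h, 7487 of the 15658 features passed, 3015 higher (40.3%) and 4472 lower, with 1471 and 1886 changed at least 2-fold. Rises were 55.2% (4020 against 3265) when the arrays were scaled to a common median, which moved the median of all features by 0.17 on the log2 scale. The count was 3584 with no filter on low probe sets, and 4251, 3866, 4094 and 3982 without the wild-type 0 h, wild-type 24 h, lcbk1-2 0 h and lcbk1-2 24 h array.

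**Figure D2:**
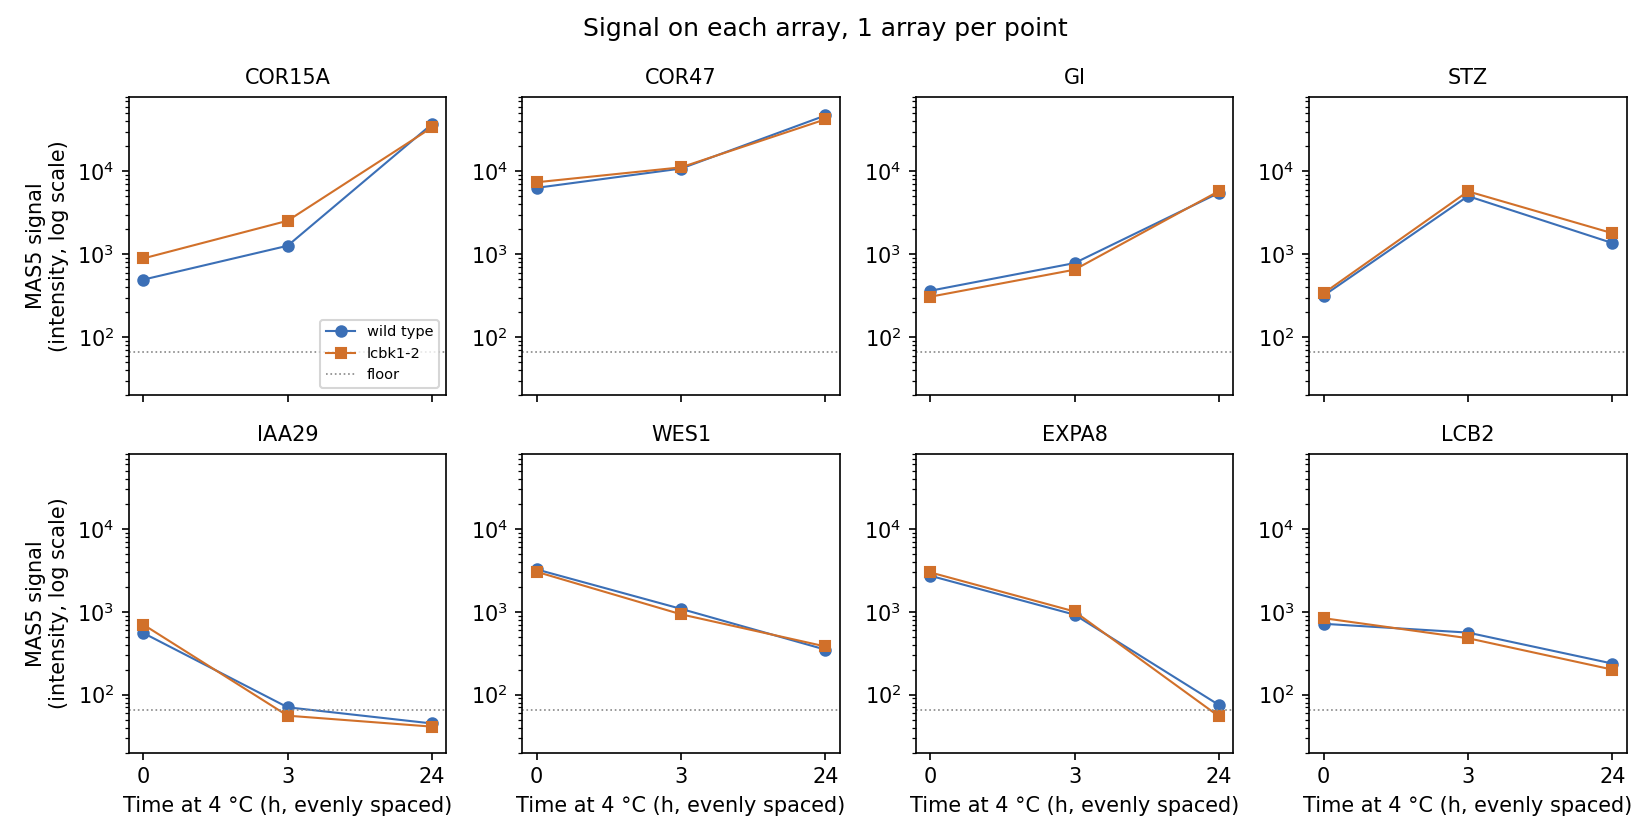
MAS5 signal (log axis) of 8 named genes on each of the 6 arrays against the time at 4 °C, wild type in circles and lcbk1-2 in squares, with the floor of 65.9 dotted; lines join arrays of 1 genotype. COR15A ran from 494 and 891 at 0 h to 37229 and 33884 at 24 h, and EXPA8 from 2719 and 2984 to 75.0 and 54.7, in the wild type and lcbk1-2.

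The comparison of 24 h with 3 h at 4 °C separates transcripts that kept changing from early ones that fell back. LEA4-5, a late embryogenesis abundant protein gene, fell at 3 h (-0.91) and then rose by 5.89 (SE 0.15, adjusted p = 6.9e-05 in limma). Its signal went from 129 to 7414 in the wild type and from 135 to 8174 in lcbk1-2. AT1G16850 rose by 6.41, AT2G22590 by 4.83, COR27 by 4.67, AT3G17130 by 4.37, COR15A by 4.31, AT1G32860 by 4.28, the defensin gene PDF2.1 by 4.12 and AT1G64890 by 4.01. AT2G38465 was at the floor at 0 h and 3 h and rose at least 15.8-fold. The falls included genes that had risen at 3 h. AT1G55960 changed by 2.16 at 3 h and then by -3.79, AT1G18740 by 2.67 and -3.54, AT5G11070 by 1.59 and -3.51, and AT1G74450 by 2.75 and -3.36. These ended below 0 h, at -1.92 to -0.61. STZ changed by -1.78 and CML38 by -2.91. Falls not preceded by a rise were those of AT4G33666 (-3.89), EXPA8 (-3.78), AT2G34620 (-3.69), AT5G57785 (-3.55), AT2G20670 (-3.40) and AT5G19120 (-3.36). The 6 COR genes rose again, over all genes and adjusted over the list alone (median 3.15, camera adjusted p = 8.0e-06; adjusted p = 0.356 with an estimated correlation). Of 5 auxin and growth genes 3 fell, WES1, HAT2 and EXPA8, with 3 when adjusted over the list alone (camera adjusted p = 0.126; adjusted p = 0.597 with an estimated correlation). In the sphingolipid list 5 fell and 2, ATCES1 and AT1G01230, rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.265; adjusted p = 0.726 with an estimated correlation). Of these falls, the call of TSC10B was lost with a floor at the 50th percentile (-0.13) and that of AT1G07380 with that floor (-0.28), a floor at the 20th percentile, quantile normalization and median scaling. Of the rises, the call of AT1G01230 (0.54) was lost with a floor at the 20th percentile. PEX4 rose by 0.93 and NDB2 by 1.21, and WRKY53 (0.43) and PDF1.2 (0.51) passed only when adjusted over their lists alone.

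Of the 15658 features, 5326 passed between 3 h and 24 h, 2015 higher (37.8%) and 3311 lower, 842 and 1319 of them at least 2-fold. Rises made up 48.7% (2510 against 2643) under quantile normalization and 58.4% (3114 against 2214) under median scaling, which moved the median of all features by 0.18. The count was 1584 with no filter on low probe sets and 2195, 1310, 2244 and 1087 without the wild-type 3 h, wild-type 24 h, lcbk1-2 3 h and lcbk1-2 24 h array.

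The response to cold was then set side by side in the wild type and lcbk1-2, the comparison that asks whether loss of the kinase alters it. COR15B changed by 5.72 at 24 h in the wild type and by 5.90 in lcbk1-2, and STZ at 3 h by 3.99 and 4.08. GI changed at 24 h by 3.92 and 4.23, EXPA8 at 24 h by -5.18 and -5.50, and LCB2 at 24 h by -1.59 and -2.06. COR15A started higher in lcbk1-2, at 891 against 494, and changed by 5.25 against 6.23. The COR list's median at 24 h was 4.61 in the wild type and 4.35 in lcbk1-2, and that of the auxin and growth list -3.07 and -2.99. The sphingolipid list's median at 24 h was -0.47 in the wild type, at percentile 14.2 of random lists, and -0.84 in lcbk1-2, at percentile 1.41. The difference was not tested. At 3 h 1150 features were at least 2-fold apart from 0 h in the wild type (693 higher, 457 lower) and 1312 in lcbk1-2 (813 and 499). At 24 h these were 3552 (1525 and 2027) and 3566 (1537 and 2029). Among the tested features, 504 were at least 2-fold higher and 273 lower in both genotypes at 3 h, against 35.8 and 14.4 for independent lists. At 24 h these were 1197 and 1472, against 149 and 262, and 0 went in opposite directions. These comparisons share no array. Over features at least 2-fold changed in either genotype, the principal axis of the paired changes, which treats the genotypes alike, had a slope of 1.07 at 3 h and 1.01 at 24 h. Over those at least 2-fold changed in the wild type, the median ratio of the change in lcbk1-2 to that in the wild type was 0.939 and 0.933. In all, 148 features at 3 h and 271 at 24 h differed at least 2-fold in their change, with no test possible for 1 array per condition.

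Between the genotypes, the differences shared by all 3 times were few and small beside the cold. A pair of probe sets passed in limma, both unnamed here and chosen after their values were seen. The probe set 259813_at was higher in lcbk1-2 at all 3 times (log2 difference 1.92, SE 0.11, adjusted p = 0.0211), with signals of 553, 387 and 233 against 147, 94.3 and 49.9, the last below the floor. The probe set 267565_at lay below the floor on all 3 lcbk1-2 arrays and at 249, 256 and 216 in the wild type, at least 3.63-fold lower in lcbk1-2 (adjusted p = 0.0211). It passed the filter through the wild-type arrays alone, so its direction was fixed by the filter. Its lcbk1-2 values, set to the floor, did not vary, which can make its SE and p too small. Among annotated genes, 0 of which passed in limma, the chitinase-family gene CHI (AT2G43570) was at -1.12 (SE 0.12, adjusted p = 0.160) and the peroxidase gene AT5G64120 at -1.36 (adjusted p = 0.160), each lower in lcbk1-2 at all 3 times. AT1G67865 (0.97), AT3G15780 (0.93) and AT2G47880, a glutaredoxin-family gene (0.98), were higher at all 3 times and did not pass. AT1G67865 and AT3G15780 were chosen after their values were seen. In all, 2 of 15658 features passed, against 1292 at an unadjusted p under 0.05 and 783 given by chance. Both calls were lost with a floor at the 20th percentile or none, at differences no smaller (2.06 and -2.79 for 259813_at and 267565_at), without the filter, at the same differences, with a floor at the 50th percentile (1.22 and -0.60), and without any 1 array, where 0 passed in limma beside 847 to 1062 at an unadjusted p under 0.05, and 23 and 24 features passed with a pseudocount or a mean-variance trend.

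Of the sphingolipid genes, 0 of 10 passed over all genes in limma and 0 when adjusted over the list alone, with a median of -0.08, DPL1 at -0.25 and TSC10B at -0.33 (camera adjusted p = 0.332; adjusted p = 0.726 with an estimated correlation). At single times the list's median was -0.17 at 3 h and -0.20 at 24 h, at percentiles 1.58 and 1.68 of random lists, and 0.09 at 0 h, at percentile 79.7. Over all lists and comparisons of 1 array against 1, 46 of 203 medians lay outside the central 95% of random lists, against 10.15 for lists of unrelated genes. In the flavonoid list, UF3GT and AT5MAT lay at the floor on all wild-type arrays and passed the filter through lcbk1-2 arrays alone, so their direction was fixed by the filter. Without them, in a test chosen after the values were seen, the other 3 members had a median of 0.67 (camera adjusted p = 0.00827; adjusted p = 0.402 with an estimated correlation), beside 0.55 for all 5 (camera adjusted p = 8.1e-04; adjusted p = 0.356 with an estimated correlation). DFR, a reductase of anthocyanin synthesis, was at 0.68, AT4G14090 at 0.67 and UGT78D2 at 0.30, with 0 past the threshold over all genes in limma and 2, DFR and AT4G14090, adjusted over these 3 alone. Adjusted over their lists alone, AT2G21640 (-0.57) and NDB2 (-0.26) of the oxidative stress list and ATSPS4F (0.52) also passed. Signals of UF3GT, AT5MAT, AT4G14090 and DFR lay near or below the floor on several arrays. COR genes (median 0.08, camera adjusted p = 0.645; adjusted p = 0.726 with an estimated correlation) and auxin and growth genes (median 0.03, camera adjusted p = 0.843; adjusted p = 0.864 with an estimated correlation) did not differ past the threshold.

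At single times, 112 of 22589 features were at least 2-fold apart at 0 h (50 higher and 62 lower in lcbk1-2), 116 at 3 h (68 and 48) and 131 at 24 h (76 and 55), with no replicate check. Among tested features, 4 were higher and 10 lower at both 0 h and 3 h, against 0.217 and 0.164 for independent lists. For 0 h and 24 h these were 6 and 6, against 0.236 and 0.197, with 2 in opposite directions. For 3 h and 24 h they were 5 and 8, against 0.321 and 0.155, with 1 opposite. These times share no array. AT4G15680, a glutaredoxin-family gene, read 213 in lcbk1-2 against 624 at 0 h, 103 against 636 at 3 h and 102 against 191 at 24 h. AT5G64120 was among the 10 lowest at each time, at -1.23, -1.74 and -1.12. At 0 h CCS, the copper chaperone of superoxide dismutase, was at -1.57, the lectin-like AT1G52100 at -1.35 and AT2G28780 at 1.31. The chloroplast-encoded petL was at 4.25, from a wild-type 0 h signal of 66.3 that stood beside 908 and 909 at the later times; ndhE was at 1.59 and atpF at 1.27, on the array whose hybridization controls read 2.21 times the others. At 3 h GAT1_2.1 was at -1.89, the chitinase-family gene AT2G43620 at -1.26, AT1G79770 at 1.33 and AT1G52000 at 1.32. At 24 h AT1G30700, a berberine bridge enzyme-like gene, was at -1.54, the glycosyltransferase gene UGT73C1 at -1.20, AT2G36690 at -1.19, the chloroplast-encoded psbT at 1.73 and AT5G48240 at 1.11.

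**Figure D3:**
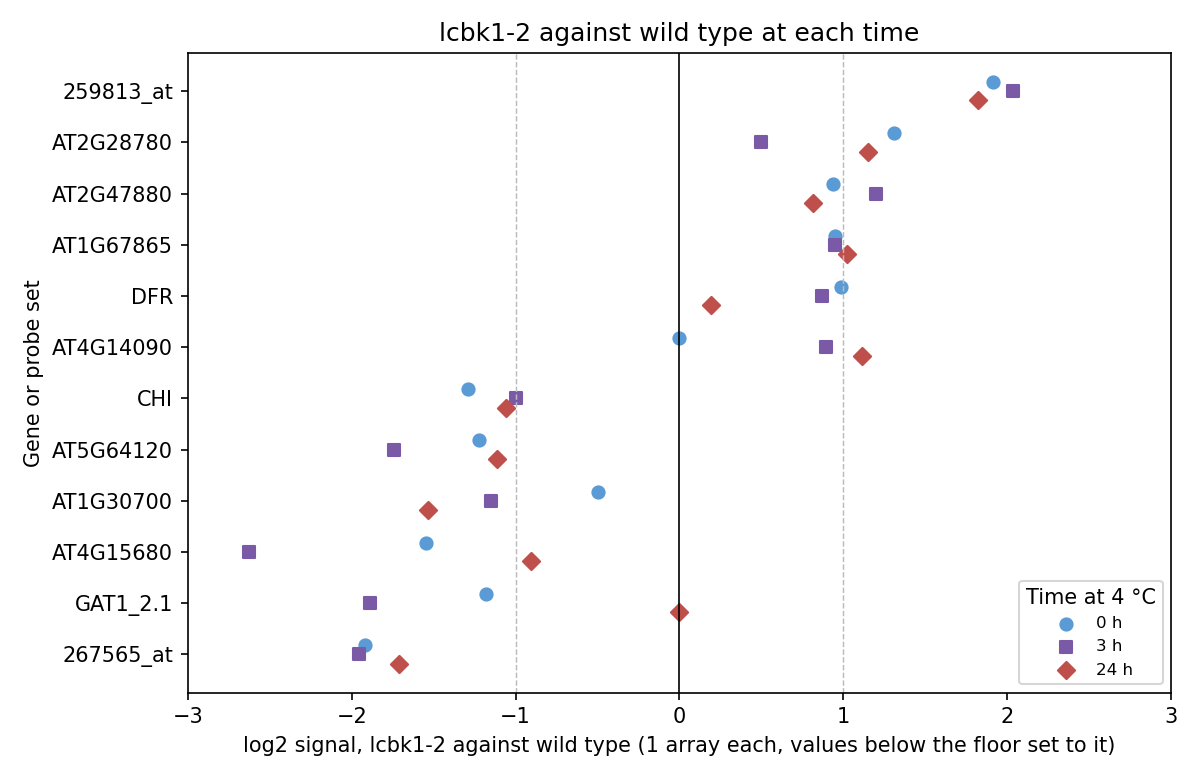
log2 difference in signal between lcbk1-2 and wild type for 12 named genes or probe sets at 0 h (circles), 3 h (squares) and 24 h (diamonds), 1 array against 1, with signals below the floor set to it and dashed lines at a 2-fold difference. AT4G15680 ran from -2.63 to -0.91 and 259813_at from 1.82 to 2.04.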

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

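The test in this part, a count over other groupings of the arrays, was chosen before its result was seen. A pair of features was at least 2-fold lower in lcbk1-2 at 1 time and at least 2-fold higher at another, with 1 array for each genotype and time, and was chosen for that after the values were seen. The unnamed probe set 247949_at differed by -1.64 on the log2 scale at 0 h and by -1.89 at 3 h, but by 1.05 at 24 h, with signals of 83.6, 91.4 and 499.8 in lcbk1-2 and 259.8, 338 and 242 in the wild type. AT1G78010 differed by -1.11 at 0 h and by 1.05 at 24 h, as its wild-type signal went from 184 to 70.8 and its lcbk1-2 signal from 85.3 to 146. The difference between the times was not tested, since no genotype and time had a second array. For the change with cold, 0 features moved at least 2-fold in opposite directions in the genotypes, at 3 h or at 24 h.

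The genotype count was set against other groupings of the arrays. In limma, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave 2 features, and the highest of the others gave 0. With 10 splits, a share under 0.05 cannot be reached. Most of the other splits also put both arrays of 1 time on the same side, unlike the real one. With time in the fit, their groups are then compared at a single time. In the rest, any genotype difference enters the residual. The comparison therefore cannot decide whether the 2 features arose by chance.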

How the results depend on the processing

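The tests on the 22 added lists, which include the tetraspanins, and those on list members off the floor in both genotypes were chosen only after the result was seen. With 1 array per genotype and time and 2 residual degrees of freedom, precision is limited by the number of arrays, and below the floor of 65.9 by the background. Both limits showed in the counts of features past the threshold. Without a filter on low probe sets, the change at 3 h went from 2687 to 124 features, at 24 h from 7487 to 3584, and from 3 h to 24 h from 5326 to 1584; features near the background then enter the prior, whose degrees of freedom went from 4.16 to 0.380. An added 2-fold threshold left 1054, 3357 and 2161 by construction. At 3 h, 1018 passed with a floor at the 20th percentile and 1546 with none. Leaving out 1 array gave 0 to 486 features at 3 h, 3866 to 6539 at 24 h, 1087 to 3944 from 3 h to 24 h, and 0 to 0 for the genotype, since 1 residual degree of freedom remained. For the genotype, 2 features passed, against 0 with a floor at the 20th or 50th percentile, no floor, no filter, or genotype alone in the fit (142 to 1483 at an unadjusted p under 0.05 in limma), and 23 with a pseudocount and 24 with a mean-variance trend.

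Counts of features at least 2-fold apart, 1 array against 1, moved with the floor. For the wild type at 3 h the count went from 1150 to 1896 with a floor at the 20th percentile, 5095 with none and 337 at 3-fold; with no floor and at 3-fold it went from 3552 to 8015 and 1513 at 24 h, and in lcbk1-2 from 1312 to 4861 and 432 at 3 h and from 3566 to 7676 and 1560 at 24 h. For lcbk1-2 against wild type at 0 h, 3 h and 24 h, the counts of 112, 116 and 131 became 705, 587 and 990 with a floor at the 20th percentile, 36, 41 and 29 at the 50th, 3893, 3575 and 4089 with none, 44, 47 and 42 with a pseudocount, and 8, 11 and 7 at 3-fold. The features whose cold response differed at least 2-fold between genotypes went from 148 at 3 h and 271 at 24 h to 837 and 1362 (20th percentile), 38 and 71 (50th), 545 and 957 (none) and 40 and 91 (pseudocount). The correlation of the responses went from 0.797 at 3 h to 0.655, 0.850 and 0.713 (20th, 50th, none) and from 0.910 at 24 h to 0.829 and 0.856 (20th, none). Of 116 tests of gene lists, 88 of them on added lists, 14 passed, 7 of them on added lists, at the preset correlation and 0 with an estimated one. With 2 residual degrees of freedom the estimated form had little power, so its count does not decide between them. The median of the tetraspanin genes at 24 h, negative in both genotypes, was 0.12 in the wild type and 0.14 in lcbk1-2 with a floor at the 20th percentile. A lower floor cannot turn the fall of a probe set into a rise. It did admit dimmer features to the tests (19442 against 15658), so these medians need not cover the same genes. Apart from what the construction of a setting shows, the cause was not tested.

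Named genes gave 424 values with a test. With the alternatives that kept all arrays, 3786 values stayed on the same side of the threshold. Of the others, 388 were no longer past it and 28 were newly past it. Leaving out 1 array gave 1778, 765 and 1. For list medians with a test, all arrays kept, these counts were 804, 2 and 5. Direction was compared only for values past the threshold with the main settings. A value that did not pass may therefore have changed its sign and still be counted on the same side. The principal-axis slopes for the paired responses of the genotypes, 1.07 at 3 h and 1.01 at 24 h, moved little. Under the alternatives run on them they lay between 1.03 and 1.09 at 3 h and between 0.969 and 1.01 at 24 h.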

Other observations

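The gene families in this part and the 4 tests on chloroplast-encoded genes were chosen only after the result was seen; the tests on starvation, low-oxygen, chitinase and berberine bridge enzyme-like genes were chosen before theirs were seen. Families added by gene symbol or locus made 22 lists and 88 tests in camera, of which 7 passed at the preset correlation and 0 with an estimated one. The estimated form had little power with 2 residual degrees of freedom. Each 95% interval in this part comes from 10000 bootstrap draws over the genes of a list. It treats genes that move together as separate, and the error of the arrays does not enter it.

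Of 8 measured autophagy genes, 3 fell at 3 h (ATG8E by -1.53 on the log2 scale, ATG8F by -0.89 and ATG8C by -0.61, the last 2 lost with a floor at the 20th percentile), with a list median of -0.43 (camera adjusted p = 0.0122; adjusted p = 0.985 with an estimated correlation). At 24 h 5 fell, ATG8E (-3.10, SE 0.13), ATG8F (-2.21), ATG8C (-1.16), ATG3 (-0.76) and ATG8B (-0.51, a call lost under quantile normalization, median scaling and several other alternatives), and ATG8D rose by 1.04 (camera adjusted p = 0.181; adjusted p = 0.985 with an estimated correlation). The 4 measured ribosome biogenesis genes rose at 24 h: AT3G15460 by 2.30, AT3G05060 by 1.59, AT5G14520 by 1.05 and AT1G52930 by 0.89 (median 1.32, camera adjusted p = 0.0122; adjusted p = 0.985 with an estimated correlation). Among 15 expansin genes, EXLA1 (1.77), EXLA2 (1.79) and EXLA3 (2.27) rose at 24 h. Of the others 8 fell, 6 under quantile normalization and median scaling, among them EXPA4 (-2.62), EXPB3 (-1.88) and EXPA9 (-1.18) (camera adjusted p = 0.519; adjusted p = 0.985 with an estimated correlation). Of 10 genes of the calmodulin-binding IQD family 7 fell at 24 h, 6 under quantile normalization and median scaling, with IQD30 at -1.41 and IQD22 at -1.32, and IQD23 rose by 1.40 (camera adjusted p = 0.181; adjusted p = 0.985 with an estimated correlation). In 7 calmodulin-like genes, CML37 (1.53) and CML38 (0.56, a call lost with a floor at the 20th percentile or none) rose at 24 h, and CML43 (-1.53, lost with a floor at the 50th percentile, at -0.35), CML30 (-1.50) and CML42 (-1.25) fell (camera adjusted p = 0.753; adjusted p = 0.985 with an estimated correlation). The 9 measured ribosomal protein genes had a median of -0.17 in lcbk1-2 against wild type (camera adjusted p = 0.00712, 0.188 under quantile normalization; adjusted p = 0.985 with an estimated correlation), and none of them passed singly in limma.

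Several of the deepest falls at 24 h, such as AT4G27450, AT2G20670 and AKINBETA1, are genes known to be induced by sugar starvation, and the wider response may have fallen too. Of 35 other genes of that response listed before their values were seen, 9 were tested and 9 fell, with a median of -1.81 (95% interval -3.12 to -1.06), at percentile 0 of random lists matched on expression, which ignore that such genes move together. They were MCCA (-3.32, SE 0.14, adjusted p = 4.2e-05), AT5G63190 (-3.12), AT3G15450 (-2.48), ATL8 (-2.36), MCCB (-1.81), IVD (-1.80), AT5G24490 (-1.44), AT1G62510 (-1.06) and AT2G30600 (-0.84). MCCA, MCCB and IVD encode enzymes of leucine breakdown in mitochondria. Whether the cold, the time of day or the sugar of the medium lies behind the fall was not tested. The labels give 2% sucrose for all 6 arrays. Sampling from 1 start would place 0 h and 24 h at the same time of day, but the labels give no sampling times.

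Falls of AT1G33055 and AT3G10020 at 3 h raised the hypothesis that genes of the response to low oxygen may be lower as a group. Of 40 such genes 11 were tested; their median of -0.17 (95% interval -1.13 to 0.53) lay at percentile 17.86 of random lists. Singly, 2 rose (AT4G17670 by 2.26 and AT1G74940 by 0.69) and 3 fell (AT3G27220 by -1.30, AT1G19530 by -1.29 and AT4G39675 by -1.13), which leaves the hypothesis undecided. In lcbk1-2, the low values of CHI, AT2G43620 and AT1G30700 raised the hypothesis that chitinase and berberine bridge enzyme-like genes may be lower as families. Of 35 other such genes 15 were tested; their median of -0.17 (95% interval -0.41 to 0.08) lay at percentile 0.06 of random lists, which ignore that members move together, and none of them passed the threshold singly in limma.

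Chloroplast-encoded transcripts stood higher in the cold: of 47 genes 13 rose at 3 h (median 0.48, camera adjusted p = 5.4e-04; adjusted p = 0.985 with an estimated correlation) and 16 rose and 1 fell at 24 h (median 0.34, camera adjusted p = 0.00712, 0.112 under quantile normalization with 16 and 3; adjusted p = 0.985 with an estimated correlation). The wild-type 0 h array, whose hybridization controls read 2.21 times the others, is argued against as the whole cause by lcbk1-2 alone, with a median of 0.45 at 3 h (95% interval 0.21 to 0.73; wild type 0.32) and 0.44 at 24 h (0.29 to 0.69; wild type 0.27, -0.06 to 0.56), but it stays open for single genes such as petL, at 3.78 in the wild type and 0.12 in lcbk1-2 at 3 h, and atpF (1.22 and 0.01). Both lcbk1-2 medians rest on the same lcbk1-2 array at 0 h, so they are not independent of each other, and an error of that array was not tested. At 3 h, scaling between arrays is argued against by medians of 0.52 under quantile normalization and 0.47 under median scaling. There 15 and 13 genes had risen and 0 fallen in limma. At 24 h the median of 0.33 (95% interval 0.16 to 0.63) under quantile normalization argues against scaling as the cause of the rise from 0 h. The list's call above other genes in camera was lost there, so for that call scaling stays open. Median scaling gave 0.53 at 24 h, but it raised the median of all features by 0.17, so it could not count against scaling. More labelling of RNA without poly(A) tails, tested at 24 h, was left undecided. The 25S ribosomal RNA control, 1 probe set, went against it, with a mean change of -0.32 (-0.54 in the wild type, -0.11 in lcbk1-2). The 10 mitochondria-encoded genes, with a median of 0.25, went with it. The 24 poly(A) control probe sets read lower at 24 h than at 0 h, at a geometric mean of 243 against 296 in the wild type. In lcbk1-2 these were 247 against 281. An effect of cold or of age also stays open, untested. So does the time of day, at 24 h only if sampling did not run from 1 start.

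In lcbk1-2 against wild type the 47 chloroplast-encoded genes lay above other genes over the 3 times (median 0.26, camera adjusted p = 4.0e-08; adjusted p = 0.985 with an estimated correlation), and none of them passed singly in limma. At single times the median was 0.11 at 0 h (95% interval 0.01 to 0.34), 0.17 at 3 h (0.11 to 0.27) and 0.28 at 24 h (0.19 to 0.39). Some single genes differed most at 0 h, against the array whose controls stood apart: petL was at 4.25, 0.59 and 0.33, ndhE at 1.59, 0.57 and 0.84, and atpF at 1.27, 0.05 and 0.56 at 0 h, 3 h and 24 h. The cause was not tested.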
